A study of Danio rerio with 20 samples.

How the data were processed

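Small RNA from whole zebrafish of the TL strain was measured on 2-colour microRNA arrays in 20 samples, each sample being one dye channel of an array. Per the labels, RNA was extracted with the miRVana kit from 10 fish per cohort, and a service provider (LC Sciences) size-selected the small RNA, added a poly(A) tail, ligated a tag and stained it with Cy3 or Cy5. Whether the samples of a group came from separate pools of fish was not established here. The n given with results counts samples, and errors and p-values treat them as independent. The scanner files hold, per the file headers, the mean and the standard deviation of spot intensity in one channel, with no background removed. The image software and scanner settings are not given in the sources used here. Each file had 3968 spots, among them the mature zebrafish microRNA probes in 12 spots each and 1048 empty spots. The deposited value table holds one processed intensity per microRNA probe and sample on a linear scale; the authors' background correction and scaling are not given in the sources used here. Its log2 values correlated at 0.990 to 0.998 per sample with the values computed here from the scanner files, so its direction is settled, while its scale and centring stay unknown. The table was used as an alternative only.

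Column medians of that table, in the authors' units, were 118 for each sapje sample at 5 dpf, 105 and 104 for wild type SW replicates 1 and 2, 111 and 102 for wild type SLW replicates 1 and 2, and 138 and 110 for sapje-like replicates 1 and 2. At 30 dpf they were 130, 144 and 109 for sapje replicates 1, 2 and 3, and 125, 121 and 141 for wild type SW replicates 2, 3 and 4. In the other cohort they were 129, 117 and 103 for wild type SLW replicates 2, 5 and 8, and 113, 120 and 95.3 for sapje-like replicates 1, 2 and 3.

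Scanner values were corrected for background by normexp with an offset of 50, taken to log2 and averaged over the 12 spots of a probe. Samples were brought to one distribution by quantile normalization over all mature microRNA probes. Quantile normalization assigns values by rank, so the brightest probes of different samples can share a value. A probe counted as above background in a sample when its mean scanner intensity exceeded the median of the empty spots by over 3 standard deviations, estimated from their median absolute deviation. Probes above background in at least 2 samples of any group were tested, which kept 167 probes, 15 of them star strands, and left out 52. The median empty spot read 282 to 572 in Cy3 and 32.3 to 47.2 in Cy5, the brightest probe 14761 to 44985, and 105 to 173 probes per sample were above background. The number of arrays limits the precision of every value. Fits were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on 8 groups plus a term for the dye, with 11 residual and 2.48 prior degrees of freedom. P-values were two-sided and adjusted by Benjamini and Hochberg over the 167 probes within each comparison, with a threshold of 0.05. Errors given with log2 differences are the standard errors of that fit. Where a probe was not above background in any sample of the dimmer group, its fold is a lower bound, computed from the mean of the brighter group and, per sample of the dimmer group, the higher of the lowest probe above background and the probe's own value. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

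Which samples shared an array is not stated in the labels and was inferred from spot residuals, the deviation of each spot from its probe's mean, over 456 spots of 38 bright probes. All 20 samples had a mutual best partner of the opposite dye, at correlations of 0.415 to 0.838, which gave 10 arrays. Each array paired a mutant with a wild type of its own cohort and age. At 5 dpf the partners carried the same replicate number. At 30 dpf sapje replicates 1, 2 and 3 shared arrays with wild type SW replicates 2, 3 and 4, and sapje-like replicates 1, 2 and 3 with wild type SLW replicates 2, 5 and 8. The pairing by replicate number was checked on probe deviations from group means. Samples of equal number correlated at 0.513 in the sapje cohort and 0.393 in the sapje-like cohort at 5 dpf. At 30 dpf they correlated at -0.209 and -0.149 (sapje replicates 2 and 3) and -0.0139 (sapje-like replicate 2) and were not on the same array. On the same measure the inferred array partners at 30 dpf correlated at -0.0904 to 0.251, so this check decides little there. That replicate numbers at 30 dpf do not mark shared arrays rests on the spot residuals. The shared array was fitted as a random block with a consensus correlation of 0.111.

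Each mutant was compared with the wild type of its own cohort at each age, and both mutants jointly with both wild types. Further comparisons were the sapje-like effect minus the sapje effect, wild type SLW against wild type SW, and 30 dpf against 5 dpf in wild type fish. The groups, comparisons, gene lists, rule for named probes and most alternatives were fixed before the data were examined. Per comparison the text names the 10 highest and 10 lowest fold changes past the threshold. Where fewer than 10 passed in all, it also names the probes of smallest p until 10 are reached. Measured miR-199 probes, list members past the threshold (at most 4 per list) and probes past it in both cohorts are named too. Of the list members past the threshold, some are given as counts. The miR-199 family was a later choice of the study and is not independent evidence.

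The lists were striated muscle, microRNAs raised in dystrophic or regenerating muscle of mammals, miR-199, miR-29, erythroid, leukocyte, nervous system, sensory (photoreceptor and hair cell), lens and pigment epithelium, epithelium, gut and liver, pancreas, endothelium, smooth muscle, cartilage, hox cluster, early embryo, let-7, miR-17-92 and related clusters, and germ line. They were written from general knowledge by microRNA number. Members of a list were also adjusted over the list alone. The 10 lists with at least 3 measured probes were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, adjusted over those 10 lists within each of 7 comparisons. The single germ line probe on the array was not kept, so that list gave no value. Probes of one family often differ by 1 or 2 bases on these arrays (let-7, miR-10, miR-27, miR-99 and miR-100, miR-133, miR-148 and miR-152, miR-194, miR-430), and a signal can be shared among them. Probe names are those of the array's design.

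On simulated data, 15 of 167 probes per size were changed in 20 runs. A log2 change of 1 was recovered in 26.7% (sapje at 5 dpf), 53.7% (sapje at 30 dpf), 57% (both mutants at 5 dpf), 71% (both mutants at 30 dpf) and 63% (age) of the changed probes. A log2 change of 2 was recovered in 74.3%, 87%, 90.3%, 97.3% and 93.3%, with 0.7, 0.55, 1.55, 2.7 and 2.45 false calls per run. The let-7 list, shifted by a log2 change of 1, was found in 95% to 100% of the runs at an unadjusted camera p under 0.05. Noise was drawn independently per probe, so this rate does not cover lists whose members vary together. The sapje-like cohort was not simulated separately.

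Alternatives covered the normalization (within each age, cyclic loess, median scaling, within-array loess), the authors' table, no background correction, both filters, the dye term, fits of each age or of only the groups compared, replicate and array blocks, the median over spots, a threshold of 0.1, and each sample left out in turn. Normalization and filter were not recomputed when a sample was left out, and the lone sample left in a group of 2 was assumed to vary like the other groups. Chosen after seeing the data were subtraction of the empty-spot median, normexp from the empty spots, within-array loess with the array block, the mean of the gut and liver list as a covariate, and the removal of 2 samples that stood apart. Probes for control RNAs were left out of the comparisons. No pair of samples had identical scanner values, and samples within a group correlated at 0.840 to 0.990.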

Results

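MicroRNA levels were measured in whole fish of 2 dystrophin-mutant zebrafish lines, sapje and sapje-like, and in wild types of the same 2 cohorts (SW for sapje, SLW for sapje-like). Dystrophin links the actin cytoskeleton of the muscle fibre to the extracellular matrix, and both lines serve as models of Duchenne muscular dystrophy. Each of the 4 genotypes had 2 samples at 5 days post fertilisation (dpf) and 3 samples at 30 dpf. Between 105 and 173 mature microRNA probes per sample were above background, and 167 were tested; each is named in the files with the prefix dre. The series title names its subject as dysregulated microRNAs in the 2 lines, which the comparisons of each mutant with its own wild type address. Values are normalised log2 intensity, and differences are log2 fold changes with standard errors from limma.

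At 5 dpf miR-21, a microRNA known for its rise in injured, inflamed and fibrotic tissue, was higher in both mutants. It rose by 1.75 ± 0.22 in sapje (3.37-fold, n = 2 against 2, adjusted p = 0.000362) and by 1.46 ± 0.22 in sapje-like (2.75-fold, n = 2 against 2, adjusted p = 0.00263). On all 4 arrays of that age the mutant channel was the higher. Over both cohorts the difference was 1.61 ± 0.16 (3.05-fold, adjusted p = 1.76e-05). If calls fell on probes independently, chance overlap of the higher calls of the cohorts would be 0.012 probes, and miR-21 was the 1 shared. Both cohorts used the same estimate of spread per probe, so such chance values, here and below, can be too low. Cyclic loess and median scaling end its joint call, with a difference of at least 1.21 and an adjusted p of at most 0.147 over all alternatives. In sapje alone the call ended with cyclic loess (1.44, adjusted p = 0.343), median scaling (1.36, 0.238), within-array loess (1.34, 0.226) and each age fitted alone (0.0682). In sapje-like alone it ended with cyclic loess (1.19, 0.691), median scaling (1.06, 0.592), within-array loess (1.14, 0.788), the authors' table (1.13, 0.473), each age fitted alone (0.172) and only the groups compared (0.995). In sapje-like it was also lost without wild type SLW replicate 1 (1.22, adjusted p = 0.0753) or sapje-like replicate 2 (1.35, adjusted p = 0.0743). Under median scaling the median of all probes was -0.29 in sapje, -0.18 in sapje-like and -0.20 in the joint comparison at this age, and under cyclic loess it was -0.10 in sapje-like.

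**Figure D1:**
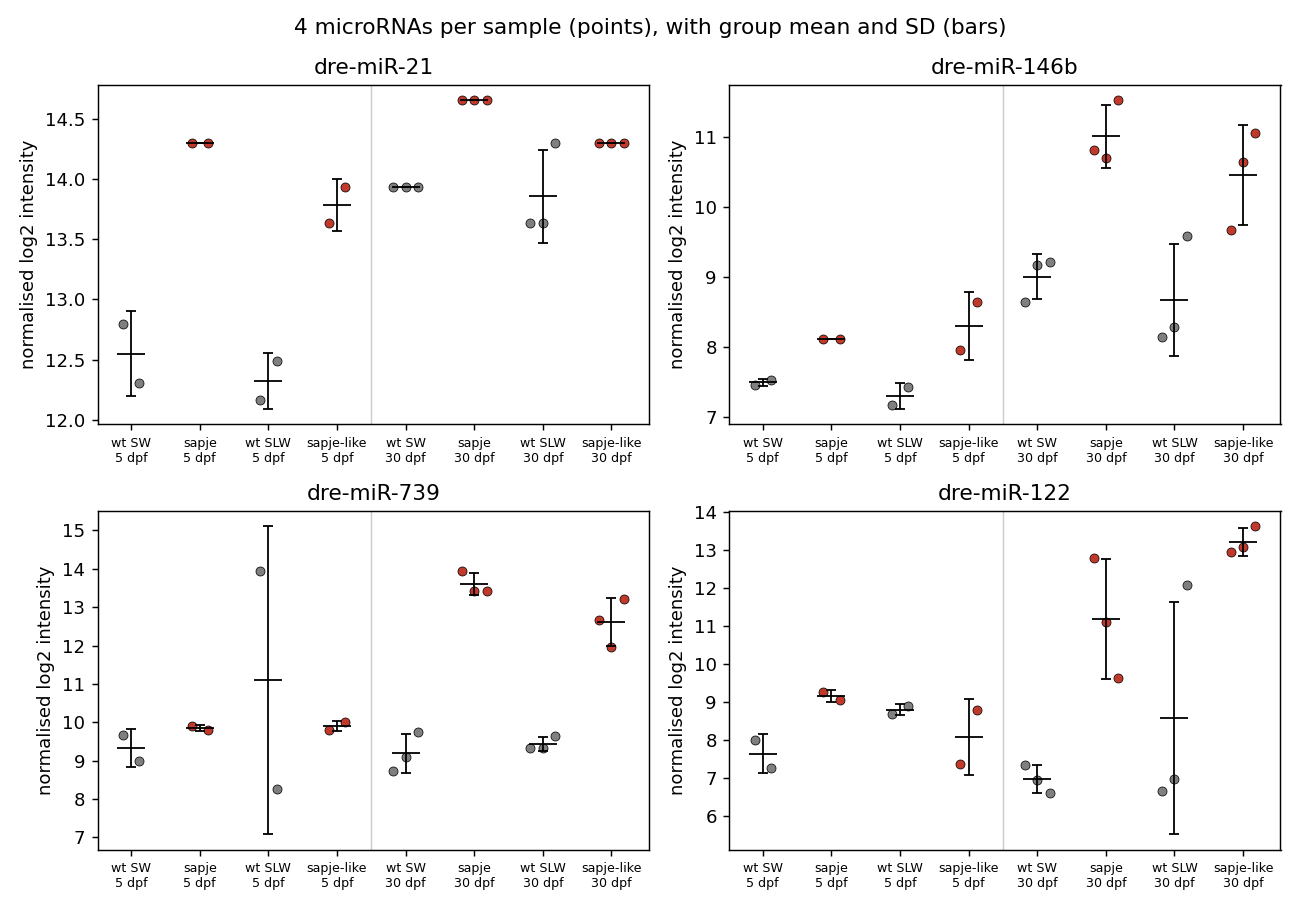
Normalised log2 intensity of miR-21, miR-146b, miR-739 and miR-122 in each of the 20 samples, by group, with group mean and SD (n = 2 per group at 5 dpf, n = 3 at 30 dpf). Joint log2 differences of mutants from their wild types were 1.61 for miR-21 at 5 dpf, and 1.91, 3.98 and 4.60 for miR-146b, miR-739 and miR-122 at 30 dpf.

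In sapje at 5 dpf, miR-1, the main microRNA of striated muscle fibres, was also higher than in wild type SW, and miR-430b, of a family that clears maternal transcripts from the early embryo, was lower. miR-1 rose by 1.48 ± 0.31 (2.79-fold, adjusted p = 0.0198) and miR-430b fell by 1.03 ± 0.17 (2.04-fold, adjusted p = 0.00293), each in 2 of 2 arrays. Of the 4 measured early-embryo probes, all of the miR-430 family, 1 fell over all probes and 2 fell when adjusted over the list alone. The list as a whole fell (mean -0.68, camera adjusted p = 0.00152), also with an estimated correlation (adjusted p = 0.0385), and fry gave 0.000483. That list call was lost with cyclic loess (adjusted p = 0.474), the authors' table (0.232) and median scaling (0.0531). Of 6 striated muscle probes 1 passed, and 1 when adjusted over the list alone (mean 0.42, camera adjusted p = 0.225); the list's median changed sign with cyclic loess, and its mean was 0.04 without sapje replicate 1 and 0.80 (camera adjusted p = 0.0301) without replicate 2. Among 11 microRNAs known to rise in dystrophic or regenerating mammalian muscle only miR-21 passed, over all probes and over the list alone. The list as a whole was not called by camera (adjusted p = 0.555), and fry's mixed test, which 1 strong member can carry, gave 0.00028. Gut and liver microRNAs averaged 1.34 higher with 0 past the threshold (camera adjusted p = 0.225).

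With limma, 3 of 167 probes passed in sapje at 5 dpf (2 higher, 1 lower), and 15 had an unadjusted p under 0.05. The next by p did not pass: miR-430a (-0.97 ± 0.26, adjusted p = 0.104), miR-26b (0.76 ± 0.26), miR-218a (0.90 ± 0.33), miR-199* (0.86 ± 0.31) and miR-126 (0.80 ± 0.29), the last 4 at an adjusted p of 0.347. miR-214 (-0.55 ± 0.21, 0.356), miR-181c (-0.74 ± 0.29, 0.368) and miR-199 (-0.28 ± 0.34, 0.796) did not pass either. The miR-1 call was lost without sapje replicate 1 (1.38, adjusted p = 0.28), sapje replicate 2 (1.58, 0.108) or wild type SW replicate 1 (1.22, 0.188). The miR-430b call was lost without sapje replicate 2 (-0.93, 0.0882) or wild type SW replicate 1 (-0.85, 0.0622). Leaving out a sample gave 1 probe without sapje replicate 2 or wild type SW replicate 1, 7 probes without wild type SW replicate 2, and 5 without either wild type SLW replicate. Cyclic loess, median scaling and fitting each age alone gave 0 probes. Within-array loess left miR-430b (0 higher, 1 lower) and the authors' table left 1 higher and 0 lower.

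In sapje-like at 5 dpf only miR-21 passed (1 higher, 0 lower with limma; 6 probes at an unadjusted p under 0.05). miR-1 was -0.93 ± 0.31 and miR-23a 0.85 ± 0.30 (each adjusted p = 0.73). miR-738 (1.18 ± 0.45) and miR-146b (1.00 ± 0.50) had an adjusted p of 0.848, as had miR-20a (1.06), miR-19d (-0.68), miR-23b (0.61), miR-430j (-0.43) and miR-30a (0.35). miR-199 (-0.09 ± 0.34, 0.974) and miR-199* (0.24 ± 0.31, 0.89) did not pass. The dystrophic-muscle list was higher (11 measured, mean 0.48, camera adjusted p = 0.0228; adjusted p = 0.557 with an estimated correlation), with 1 member past the threshold and 1 when adjusted over the list alone. That list call rests on single samples: it was lost without wild type SLW replicate 1 (mean 0.20, adjusted p = 0.711) or sapje-like replicate 2 (0.40, 0.183), and without wild type SLW replicate 2 the mean was 0.75 (0.0382). It was lost too with cyclic loess (0.33, adjusted p = 0.0782), median scaling (0.30, 0.0515) and within-array loess (0.49, 0.0996). The striated muscle list averaged -0.51 (camera adjusted p = 0.121), and -0.10 and -0.92 without wild type SLW replicates 1 and 2. Without wild type SLW replicate 1 or sapje-like replicate 2 the count was 0, and without wild type SLW replicate 2 it was 10 (7 higher, 3 lower). Cyclic loess, median scaling, within-array loess, the authors' table, each age alone and only the groups compared also gave 0 probes.

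In the joint comparison at 5 dpf, miR-430b fell by 0.59 ± 0.12 (adjusted p = 0.0221, lower in 3 of 4 arrays), so that 1 probe was higher and 1 lower (16 at an unadjusted p under 0.05). The early-embryo list fell (4 measured, 1 past and 2 adjusted over the list alone, mean -0.41, camera adjusted p = 0.00483; adjusted p = 0.0651 with an estimated correlation), a list call lost without wild type SLW replicate 2 (-0.43, adjusted p = 0.089), and with cyclic loess (-0.19, 0.931), median scaling (-0.61, 0.213) and the authors' table (-0.20, 0.775). The early-embryo list averaged -0.68 in sapje and -0.15 in sapje-like. In sapje-like its mean ran from -0.27 to 0.13 over 9 scalings and background corrections, and camera called it in 0 of them. Sapje-like minus sapje was 1.53 ± 0.17 for miR-430b, 1.72 ± 0.26 for miR-430a and 0.97 ± 0.21 for miR-430j (limma adjusted p = 7.39e-05, 0.00122 and 0.0275). That contrast leaves out the wild types, which differed as well. The list averaged 8.83 in sapje-like and 7.57 in sapje, and 8.98 in wild type SLW and 8.25 in wild type SW. The mutant effects on these probes did not differ past the threshold between the cohorts. In the joint comparison miR-430a (-0.70, adjusted p = 0.12), miR-738 (1.01, 0.298), miR-184 (-0.69, 0.336), miR-92a (-0.42, 0.336) and miR-199 (-0.19 ± 0.24, 0.776) did not pass. Nor did miR-19c (-0.42), miR-26b (0.48), miR-10d* (-0.59) and miR-199* (0.55), each at an adjusted p of 0.429. The miR-430b call was lost without sapje replicate 1 (-0.64, 0.0529) or 2 (-0.54, 0.186), wild type SW replicate 1 (-0.50, 0.0823), wild type SLW replicate 1 (-0.60, 0.0589) or sapje-like replicate 1 (-0.48, 0.182). The joint count was 5 without wild type SW replicate 2 or wild type SLW replicate 2. Cyclic loess and median scaling gave 0 probes, and the authors' table gave 1.

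miR-1 was the 1 probe whose mutant effect differed between the cohorts at 5 dpf. The sapje-like effect minus the sapje effect was -2.41 ± 0.44 (adjusted p = 0.0162; 0 higher and 1 lower with limma, 9 at an unadjusted p under 0.05). miR-1 was higher in wild type SLW than in wild type SW by 2.27 ± 0.31 (4.84-fold, adjusted p = 0.000839), while sapje-like and sapje differed by -0.14 ± 0.31 (adjusted p = 1). The call on the cohort difference was lost without sapje replicate 1 (adjusted p = 0.12) or 2 (0.0598), wild type SW replicate 1 (0.144), wild type SLW replicate 1 (0.134) or sapje-like replicate 2 (0.149). Without wild type SLW replicate 2, 3 probes passed. miR-430b (0.88 ± 0.24, adjusted p = 0.226), miR-181c (1.03 ± 0.41), miR-126 (-1.01 ± 0.42), miR-430c (0.96 ± 0.41), miR-181b (0.83 ± 0.37), miR-218a (-1.04 ± 0.46), miR-205 (1.36 ± 0.62) and miR-9 (-1.68 ± 0.77), from miR-181c on at 0.898, did not pass. Quantile normalization within each age, cyclic loess, median scaling, within-array loess and the authors' table each gave 0.

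At 30 dpf both mutants carried more of miR-146b, of miR-739, and of miR-122, the main microRNA of liver. miR-146b belongs to a family known to dampen innate immune signalling, of which miR-146a differed by 0.66 and did not pass. Over both cohorts miR-146b rose by 1.91 ± 0.30 (3.76-fold) and miR-739 by 3.98 ± 0.66 (15.8-fold), each at an adjusted p of 0.00216, and miR-122 by 4.60 ± 0.81 (24.2-fold, adjusted p = 0.0027). All 3 were higher in the mutant channel of 6 of 6 arrays (n = 6 against 6). Whether the miR-739 probe reports a true microRNA was not checked here. miR-192 (4.28 ± 1.03, 19.5-fold, adjusted p = 0.0151) and miR-194a (2.82 ± 0.84, 7.04-fold, adjusted p = 0.039), known from gut and liver, were higher in 5 of 6 arrays. miR-21 was higher by 0.62 ± 0.13 (adjusted p = 0.0133, 5 of 6 arrays). miR-184, a lens and epithelial microRNA (0.90 ± 0.20, adjusted p = 0.0133), miR-18c (0.51 ± 0.12, 0.0133) and miR-92a (0.51 ± 0.12, 0.0151) were higher in 6 of 6.

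Gut and liver microRNAs averaged 3.05 higher in the mutants at 30 dpf, with 3 of 4 measured past the threshold and 3 when adjusted over the list alone. Camera called the list at its preset correlation of 0.01 (adjusted p = 0.00124). The members' deviations from their group means correlated at a median of 0.938, so that preset is too low for this list. The list was not called by camera with an estimated correlation (adjusted p = 0.55) or by fry (0.0555). The list mean was 10.21 ± 1.48 (SD, n = 3) in sapje and 7.26 ± 0.12 in wild type SW. It was 11.87 ± 0.29 in sapje-like and 8.76 ± 2.68 in wild type SLW, whose samples spanned 7.17 to 11.85, the highest being replicate 8. The pancreas and smooth muscle lists, neither of them called, were highest in the same samples. In the 5 samples highest on the gut and liver list (sapje replicate 1, wild type SLW replicate 8 and the 3 sapje-like samples, 11.59 to 12.16) the pancreas list lay between 8.00 and 8.18, against 7.22 to 7.47 in the other 7. The smooth muscle list lay between 9.57 and 10.22 in those 5, against 8.28 to 9.07. Of the 5 pancreas probes miR-217 carried most of this, at 9.27 to 9.80 against 7.04 to 7.63. Between mutants and wild types miR-375 differed by 0.73, and miR-216a, miR-216b and miR-7a by -0.01, -0.02 and 0.06. miR-122 was above background in 4 of 6 wild-type samples, so the size of its fold change is not exact.

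**Figure D2:**
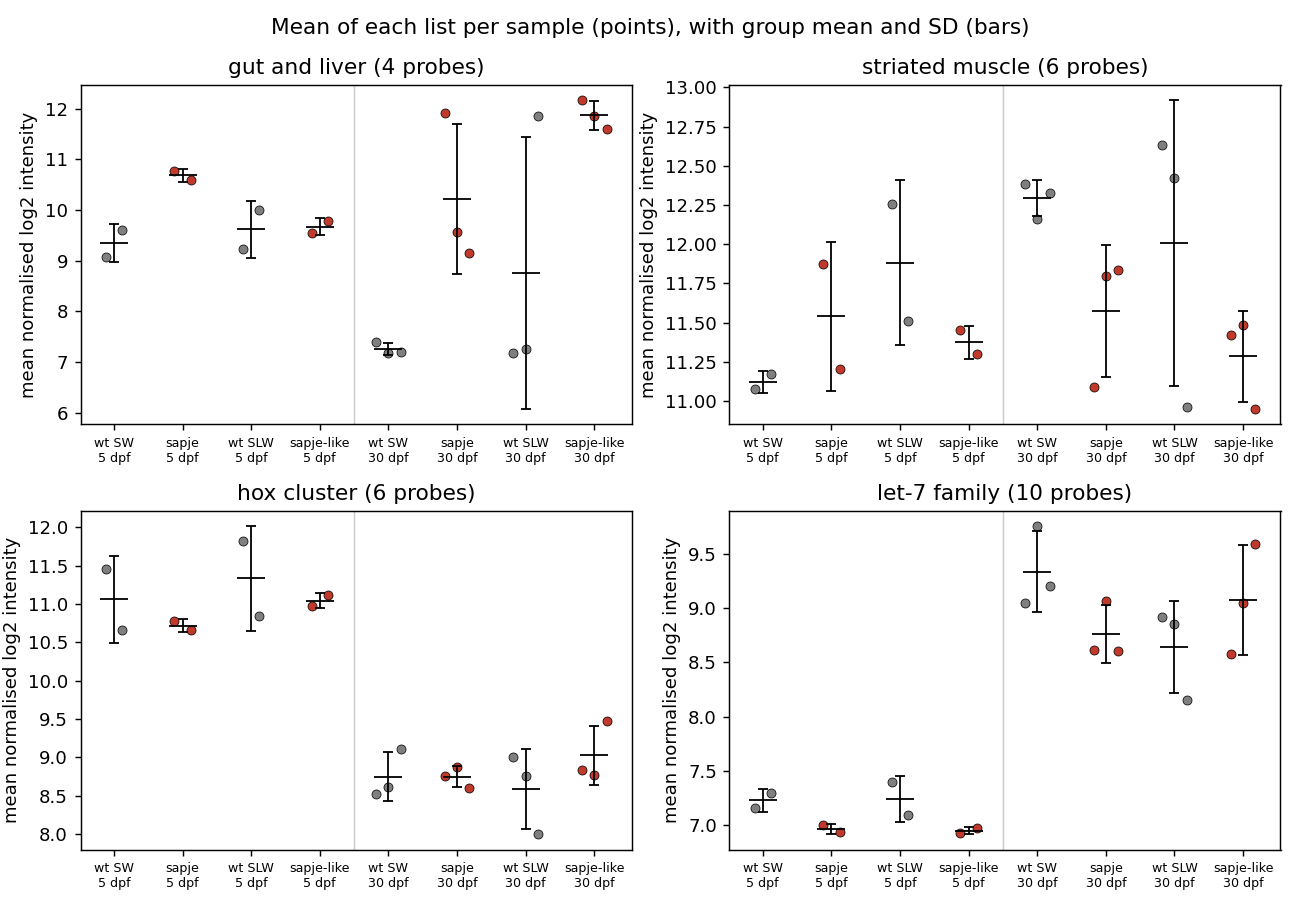
Mean normalised log2 intensity of the gut and liver (4 probes), striated muscle (6), hox cluster (6) and let-7 (10) lists in each of the 20 samples, by group, with group mean and SD. At 30 dpf the gut and liver mean was 10.21 in sapje, 7.26 in wild type SW, 11.87 in sapje-like and 8.76 in wild type SLW, with 1 wild type SLW sample at 11.85.

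Striated muscle microRNAs lay lower in the mutants at 30 dpf, with 6 of 6 probes below wild type (mean -0.72), of which miR-499, encoded in a slow myosin gene, and miR-1 passed. miR-499 fell by 1.34 ± 0.31 (adjusted p = 0.0141, lower in 6 of 6 arrays). miR-1 fell by 0.68 ± 0.19 (adjusted p = 0.0287, higher in 0 of 6 arrays). Over the list alone 2 passed, and camera did not call the list (adjusted p = 0.0777) in any of 9 scalings and background corrections, over which its mean ran from -0.74 to -0.27. The list lay lowest where gut and liver lay highest, at 10.95 to 11.48 in those 5 samples, wild type SLW replicate 8 among them, against 11.80 to 12.63 in the other 7. miR-451, the erythroid microRNA, fell by 1.07 ± 0.28 (adjusted p = 0.022, 6 of 6 arrays), and miR-15b fell by 1.18 ± 0.20 (adjusted p = 0.00216, 6 of 6). In the miR-27 family miR-27c (-0.90 ± 0.20, adjusted p = 0.0133) and miR-27a (-0.72 ± 0.17, 0.0151) were lower in 5 of 6 arrays. miR-152 (-1.36 ± 0.33, 0.0151), miR-99 (-1.12 ± 0.32, 0.0344) and miR-100 (-0.68 ± 0.19, 0.0287) were lower too. miR-199 fell by 0.73 ± 0.20 (adjusted p = 0.0317, 5 of 6 arrays) and miR-199* was -0.49 ± 0.19 (0.0936).

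In all, 22 of 167 probes passed at 30 dpf with both cohorts joined (9 higher, 13 lower), against 50 at an unadjusted p under 0.05. Split by scaling, the counts higher and lower were 10 and 6 with cyclic loess, 11 and 7 with within-array loess, 9 and 17 with quantile normalization within each age, 6 and 7 with median scaling, and 8 and 13 in the authors' table. In the authors' table the median of all probes was -0.11. Median scaling ended the calls of miR-184, miR-18c and miR-92a, cyclic loess those of miR-27a and miR-451, and each of these scalings those of miR-1, miR-99, miR-100 and miR-199. Fitting each age alone, or only the groups compared, left 8 probes, and with the shared array as a block 29 passed (11 higher, 18 lower). miR-739, miR-146b, miR-122, miR-21, miR-184, miR-92a, miR-15b, miR-27a, miR-27c, miR-499 and miR-152 passed with any 1 of the 20 samples left out. miR-18c (0.43, adjusted p = 0.051) and miR-192 (3.50, 0.0739) were lost without wild type SLW replicate 5. miR-194a was lost with any of 13 samples left out and miR-99 with any of 12, with adjusted p up to 0.132 and 0.117, both without wild type SLW replicate 5. miR-1, miR-100 and miR-199 were each lost without sapje-like replicate 2 (-0.73, -0.71 and -0.70), sapje replicate 1 (-0.58, -0.60 and -0.63), wild type SLW replicate 2 (-0.63, -0.61 and -0.62) or 5 (-0.60, -0.59 and -0.67), or wild type SW replicate 2 (-0.68, -0.66 and -0.70) or 3 (-0.69, -0.68 and -0.74). They were lost too without sapje-like replicate 1 (miR-1, -0.64) or 3 (miR-100, -0.59, and miR-199, -0.69). miR-451 was lost without sapje-like replicate 3 (adjusted p = 0.0505), sapje replicates 1 (0.0568) or 2 (0.0537), wild type SLW replicate 5 (0.0978) or wild type SW replicate 2 (0.0542). The count was 12 without wild type SLW replicate 5, 13 without sapje replicate 1, 14 without wild type SW replicates 2 or 3 or sapje-like replicate 3, and 42 (18 higher, 24 lower) without wild type SLW replicate 8. With the mean of the gut and liver list as a covariate, added after seeing the data, 1 probe passed. That covariate itself differed by 3.05 between mutants and wild types. Here and in each cohort the fit therefore takes out mutant effect whatever its source, and it does not tell what lies behind the calls.

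The other lists at 30 dpf, both cohorts joined, held few calls. The dystrophic-muscle list had miR-21 and miR-146b higher (2 past, 2 when adjusted over the list alone, mean 0.31, camera adjusted p = 0.0777, fry mixed 0.00322). Of 14 miR-17-92 related probes 2 were higher, over all probes and over the list alone, with a list median of -0.11 that turned positive with cyclic loess and median scaling (camera adjusted p = 0.834, fry mixed 0.0405). Pancreas (5 measured, mean 0.38, camera adjusted p = 0.207), epithelium (8, -0.24, 0.742), hox cluster (6, 0.28, 0.207), early embryo (4, 0.07, 0.529) and let-7 (10, -0.09, 0.834) had 0 members past the threshold and 0 adjusted over the list alone. So had the nervous system list (6, mean -0.01, camera adjusted p = 0.79), whose median turned positive with cyclic loess and median scaling. Lists of 1 or 2 measured probes gave mean differences of 0.18 for lens (miR-184 past), 0.53 for smooth muscle (0 past, 1 adjusted over the list alone), -0.06 for leukocyte, 0.02 for sensory, 0.01 for endothelium, -0.14 for cartilage and -0.02 for miR-29.

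In sapje at 30 dpf miR-739 rose by 4.60 ± 0.92 (24.2-fold) and miR-146b by 2.02 ± 0.41 (4.06-fold), each in 3 of 3 arrays (n = 3 against 3, adjusted p = 0.0216). These were the 2 of 167 probes past the threshold (2 higher, 0 lower with limma), against 18 at an unadjusted p under 0.05. With the shared array as a block 4 passed, the others being miR-21 (0.75 ± 0.19, adjusted p = 0.0711, and 0.0411 with the block) and miR-122 (4.38 ± 1.12, 0.0716, and 0.0416 with the block). miR-146a (1.66 ± 0.53, adjusted p = 0.177), miR-192 (4.26 ± 1.43, 0.191), miR-194a (2.75 ± 1.16, 0.315), miR-18c (0.54 ± 0.16, 0.16), miR-451 (-1.26 ± 0.38, 0.16), miR-1 (-0.78 ± 0.26, 0.191), miR-15b (-0.78 ± 0.27, 0.222) and miR-199 (-0.38 ± 0.28, 0.663) did not pass.

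Among lists in sapje at 30 dpf, gut and liver microRNAs were higher (4 measured, 0 past and 3 adjusted over the list alone, mean 2.98, camera adjusted p = 0.000517; adjusted p = 0.248 with an estimated correlation). The dystrophic-muscle list was higher (1 of 11 past, 3 adjusted over the list alone, mean 0.50, camera adjusted p = 0.00394; adjusted p = 0.248 with an estimated correlation). Striated muscle was lower (0 of 6 past, 0 adjusted over the list alone, mean -0.72, camera adjusted p = 0.0232; adjusted p = 0.398 with an estimated correlation), a call lost without sapje replicate 1 (-0.48, adjusted p = 0.0673) or wild type SW replicate 4 (-0.70, 0.0574). It was lost too with cyclic loess (-0.50, adjusted p = 0.15), within-array loess (-0.45, 0.23) and the authors' table (-0.60, 0.217). Among probes above background in all samples neither it (0.253) nor the dystrophic-muscle list (0.3) was called. The let-7 family was lower (9 of 10 below wild type, 0 past, median -0.69, camera adjusted p = 0.0101; adjusted p = 0.398 with an estimated correlation), lost without sapje replicate 3 (median -0.60, adjusted p = 0.103) or wild type SW replicate 3 (-0.35, 0.213). Leaving out any of the 6 samples of the comparison gave 0 probes. For miR-739 and miR-146b the adjusted p was 0.0998, 0.0558 and 0.0888 without sapje replicates 1, 2 and 3, and 0.129, 0.0812 and 0.0557 without wild type SW replicates 2, 3 and 4. The count was 4 without wild type SLW replicate 2 and 8 (7 higher, 1 lower) without wild type SLW replicate 8. Cyclic loess, within-array loess and the authors' table gave 0 probes, and with the gut and liver list as a covariate 1 passed, neither miR-739 nor miR-146b.

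In sapje-like at 30 dpf the same 2 microRNAs were higher, miR-739 by 3.36 ± 0.92 (10.3-fold, adjusted p = 0.0365) and miR-146b by 1.80 ± 0.41 (3.49-fold, adjusted p = 0.0229). Chance overlap would be 0.0719 probes for independent calls. miR-122 (4.81 ± 1.12, 28.1-fold, adjusted p = 0.0229), miR-184 (1.28 ± 0.28, 0.0229), miR-92a (0.66 ± 0.17, 0.0299) and the smooth muscle microRNA miR-145 (1.34 ± 0.38, 0.0415) were higher too. miR-122 was above background in 2 of 3 wild type SLW samples, so its fold is not exact. Lower were miR-15b (-1.58 ± 0.27, adjusted p = 0.00921), miR-27c (-1.31 ± 0.28, 0.0229) and miR-27a (-1.06 ± 0.24, 0.0229). Also lower, each at an adjusted p of 0.0299, were miR-152 (-1.83 ± 0.46), miR-499 (-1.67 ± 0.43), miR-199 (-1.07 ± 0.28), miR-100 (-1.01 ± 0.26) and miR-27b (-0.95 ± 0.25), with miR-148 (-1.07 ± 0.31) at 0.0451. Each of the 15 showed its direction in 3 of 3 arrays. miR-199*, from the other arm of the miR-199 precursor, was -0.79 ± 0.26 (adjusted p = 0.0657), and miR-375, of pancreatic islets, was 1.31 ± 0.43 (0.0657).

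With limma 6 probes were higher and 9 lower, against 46 at an unadjusted p under 0.05. With the shared array as a block 8 were higher and 16 lower. The count fell to 0 without wild type SLW replicate 2 or sapje-like replicate 2, to 1 without sapje-like replicate 3 and to 4 without wild type SLW replicate 5, and was 34 (15 higher, 19 lower) without wild type SLW replicate 8. Over these refits the adjusted p reached 0.0636 for miR-15b, 0.108 for miR-27a, miR-27c and miR-184, 0.111 for miR-146b, 0.117 for miR-122, 0.167 for miR-148, 0.142 for miR-145 and 0.141 for the other 7. Cyclic loess, within-array loess, a fit of only the groups compared, and the gut and liver covariate gave 0 probes. Under median scaling the median of all probes was 0.11.

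Gut and liver microRNAs were higher in sapje-like at 30 dpf (1 of 4 past, 3 adjusted over the list alone, mean 3.13, camera adjusted p = 0.0156; adjusted p = 0.616 with an estimated correlation), a call lost without wild type SLW replicate 5 (mean 2.16, adjusted p = 0.0928) or sapje-like replicate 1 (2.98, 0.0534), while without wild type SLW replicate 8 the mean was 4.61. The let-7 family was higher, with 10 of 10 above wild type and 0 past (median 0.44, camera adjusted p = 0.0365; adjusted p = 0.616 with an estimated correlation), while its direction in sapje was the opposite. The let-7 call rests on single samples: it was lost without wild type SLW replicate 8 (median 0.08, adjusted p = 0.323) or sapje-like replicate 3 (0.17, 0.195). It was lost too without sapje-like replicate 2 (0.42, 0.0857) or either wild type SLW sample of 5 dpf (0.42, 0.059), and without sapje-like replicate 1 the median was 0.64 (0.0021). Cyclic loess (0.41, 0.139), median scaling (0.32, 0.229) and the authors' table (0.31, 0.145) ended it as well. The test of the difference between cohorts passed 0 of 167 probes with limma (9 at an unadjusted p under 0.05, 7 higher and 2 lower). All 10 let-7 differences were positive (0.07 to 1.60), and 5 of those 9 probes were let-7. Its smallest p-values belonged to let-7e (1.30), let-7f (1.60), miR-462 (1.97), miR-223 (-1.18) and miR-146a, each at an adjusted p of 0.663. Striated muscle averaged -0.72 with 1 of 6 past, also 1 adjusted over the list alone (camera adjusted p = 0.244), and its mean ran from -0.75 to -0.04 over the scalings. Without wild type SLW replicate 8 that mean was -1.22 (camera adjusted p = 0.0342), and without replicates 2 and 5 it was -0.42 and -0.44. Pancreas (0 past, 1 adjusted over the list alone, camera adjusted p = 0.345), hox cluster (0.204) and epithelium (0.829) were not called. The hox cluster mean of 0.50 was 0.67 without wild type SLW replicate 2 (camera adjusted p = 0.0325). It was 0.19 without wild type SLW replicate 8 and 0.26 without sapje-like replicate 3. The dystrophic-muscle list, higher in sapje, averaged 0.12 in sapje-like (median -0.02), and camera called it in 0 of 9 scalings and background corrections.

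Across the 167 probes, which are not independent replicates, the log2 fold changes of the 2 cohorts correlated at r = 0.217 (rho = 0.239) at 5 dpf and r = 0.776 (rho = 0.555) at 30 dpf. They had the same sign in 59.3% and 71.3% of probes. Without the gut and liver probes r at 30 dpf was 0.605. The shared dye term alone would give 0 and 0.0345. Probes with an unadjusted p under 0.05 in both cohorts at 30 dpf numbered 7 higher, where chance gives 0.701, and 4 lower, where chance gives 1.78. These chance values take the calls of the cohorts as independent. The fit gave both cohorts the same spread per probe, so the chance values can be too low.

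**Figure D3:**
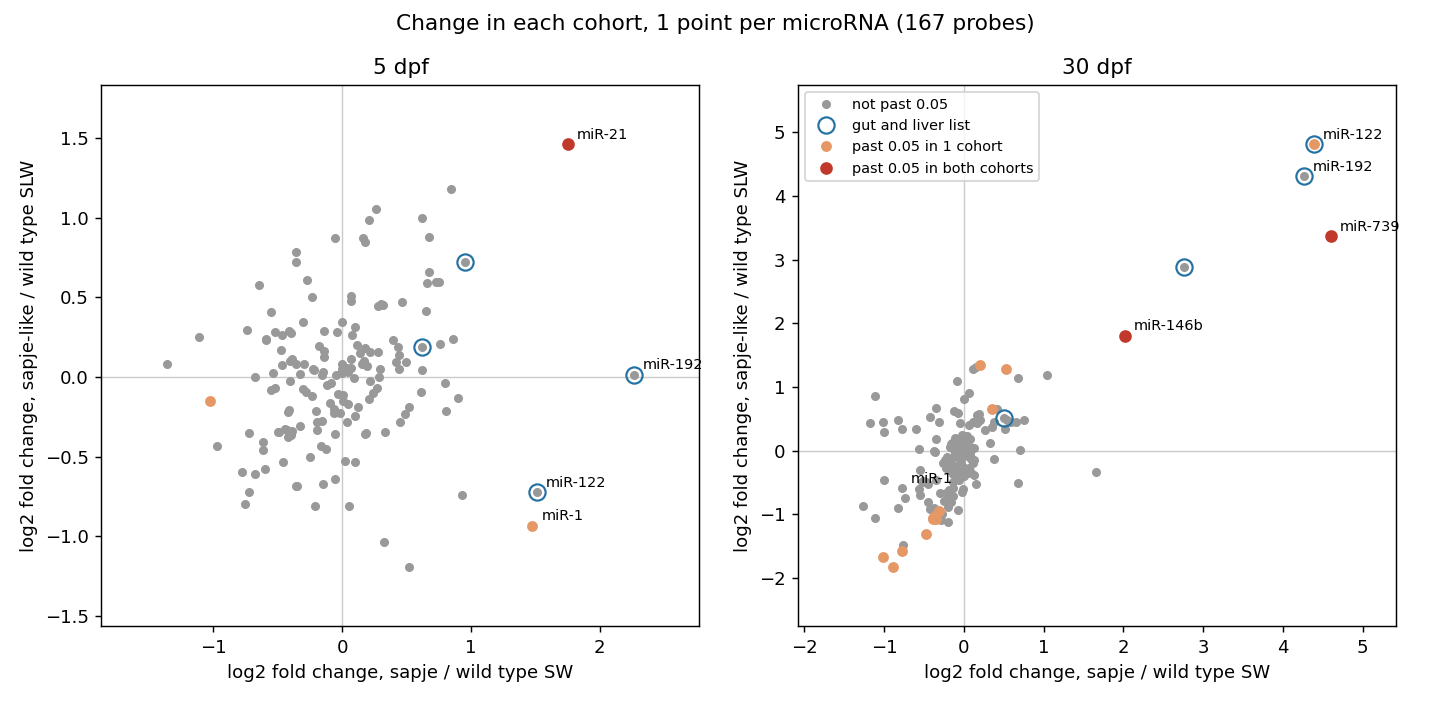
Log2 fold change of each of 167 probes in sapje against wild type SW (horizontal axis) and in sapje-like against wild type SLW (vertical axis) at 5 dpf and at 30 dpf, with probes past an adjusted p of 0.05 in 1 cohort in orange, in both in red, and gut and liver probes ringed in blue. The correlation across probes was 0.217 at 5 dpf and 0.776 at 30 dpf, and the red points are miR-21 at 5 dpf and miR-739 and miR-146b at 30 dpf.

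Between the wild types of the 2 cohorts at 5 dpf, 3 probes were higher in SLW than in SW and 0 lower (26 at an unadjusted p under 0.05). They were miR-1 (2.27 ± 0.31), miR-430a (1.18 ± 0.26, adjusted p = 0.0292) and miR-430j. miR-430j was not above background in wild type SW, so that it was at least 1.99-fold higher in SLW (adjusted p = 0.00431). Next by p, and not past, were miR-454a (0.81 ± 0.20, adjusted p = 0.06), miR-430b (0.65 ± 0.17, 0.0642), miR-454b (1.55 ± 0.42, 0.0712), miR-34 (-1.17 ± 0.33, 0.0723), miR-103 (-1.09 ± 0.31, 0.0723) and miR-9 (1.82 ± 0.55, 0.0957). The miR-430a and miR-430j calls were lost without wild type SW replicate 2 (adjusted p = 0.187 and 0.0795) or wild type SLW replicate 1 (0.288 and 0.0711). The count was 1 without either of these samples, 5 without wild type SW replicate 1 or without SW replicate 2 of 30 dpf, 7 without either sapje-like replicate, and 28 (10 higher, 18 lower) without wild type SLW replicate 2. Cyclic loess and median scaling gave 0 probes, and 1 passed in the authors' table. At 30 dpf let-7j fell by 0.75 ± 0.14 in SLW against SW (adjusted p = 0.0193), the only probe past the threshold (15 at an unadjusted p under 0.05). miR-30d (0.64 ± 0.19, adjusted p = 0.366), miR-128 (0.56 ± 0.20, 0.539) and let-7g (-0.98 ± 0.36, 0.539) came next. The let-7j call was lost without any of the 6 samples: the adjusted p was 0.0739, 0.16 and 0.0972 without wild type SW replicates 2, 3 and 4, and 0.0523, 0.108 and 0.121 without wild type SLW replicates 2, 5 and 8. Under median scaling the median of all probes was -0.33 at 5 dpf and 0.25 at 30 dpf.

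Between 5 and 30 dpf wild-type fish lost embryonic and patterning microRNAs and gained the let-7 family, known to rise as tissues differentiate. By the inferred pairs no array held samples of both ages, so differences between ages cannot be parted from differences between arrays. All 4 early-embryo probes fell, and 4 when adjusted over the list alone (mean -2.10, camera adjusted p = 0.00119; adjusted p = 0.0564 with an estimated correlation). miR-430b fell by 3.18 ± 0.11 (adjusted p = 2.79e-11, n = 6 against 4), a size that is not exact because 1 of 6 samples of 30 dpf was above background, and miR-430a, miR-430c and miR-430j, not above background in any wild-type sample at 30 dpf, were at least 5.24-fold, 3.12-fold and 1.52-fold lower. All 6 probes of the hox cluster list, the miR-10 and miR-196 families encoded among hox genes, fell, and 6 when adjusted over the list alone (mean -2.56, camera adjusted p = 0.00116; adjusted p = 0.184 with an estimated correlation). miR-10a fell by 3.56 ± 0.26 (adjusted p = 8.76e-08). All 10 let-7 probes rose, and 10 when adjusted over the list alone (mean 1.76, camera adjusted p = 0.000414; adjusted p = 0.184 with an estimated correlation), among them let-7a by 2.99 ± 0.31 (adjusted p = 1.85e-06) and let-7i by at least 3.57-fold.

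Of the nervous system list 4 of 6 fell, with miR-9 at -3.32 ± 0.35 and miR-124 at -1.56 ± 0.19, and 4 when adjusted over the list alone (mean -1.12, camera adjusted p = 0.0533, fry 1.27e-06). The erythroid miR-451 rose by 2.71 ± 0.30 and miR-223, a myeloid microRNA, by 1.99 ± 0.25, and miR-462 rose by 3.68 ± 0.43. miR-146a and miR-731, not above background at 5 dpf, rose at least 4.63-fold and 4.42-fold. miR-15b (2.44 ± 0.21), miR-738 (2.24 ± 0.29), let-7f (3.00 ± 0.36), let-7c (2.17 ± 0.37), miR-21 (1.44 ± 0.15), miR-199 (1.24 ± 0.22), miR-199* (1.70 ± 0.20) and miR-375 (1.48 ± 0.34) rose as well. miR-1 (1.56 ± 0.20), let-7j and the endothelial miR-126 (0.95 ± 0.19) rose, calls that median scaling ends. miR-9* (-3.27 ± 0.20), miR-184 (-2.77 ± 0.22), miR-10d (-3.37 ± 0.30), miR-10b (-3.03 ± 0.32), miR-10c (-2.12 ± 0.18) and miR-18c (-1.77 ± 0.13) fell. miR-192 fell by 2.87 ± 1.12 (adjusted p = 0.0401), a call lost with any of 12 samples left out (adjusted p up to 0.125, without wild type SLW replicate 5).

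Of the other lists with age, striated muscle had 1 of 6 higher (1 adjusted over the list alone, mean 0.65, camera adjusted p = 0.398). The dystrophic-muscle list had 5 higher and 1 lower of 11 (5 and 1 adjusted over the list alone, camera adjusted p = 0.212), with a median that changed sign under median scaling. In miR-17-92 and related clusters 5 of 14 fell (5 adjusted over the list alone, camera adjusted p = 0.192). Gut and liver averaged -1.48 with 1 of 4 lower (0 adjusted over the list alone, camera adjusted p = 0.398; -2.22 without wild type SLW 30 dpf replicate 8, adjusted p = 0.0826), pancreas had 1 of 5 higher (1 adjusted over the list alone, 0.665), and epithelium had 1 of 8 higher and 2 lower (1 and 0 adjusted over the list alone, 0.974). Both sensory probes fell (mean -1.02), miR-183 and miR-182, known from photoreceptors and hair cells. The smooth muscle miR-145 fell by 0.87 ± 0.30, lost without wild type SLW 5 dpf replicate 1 (-0.66, adjusted p = 0.115), wild type SW 5 dpf replicate 1 (-0.70, 0.109) or wild type SW 30 dpf replicate 3 (-0.79, 0.0581). Cartilage (miR-140, 0.14) and miR-29a (0.15) did not pass. In all 50 probes rose and 47 fell (105 at an unadjusted p under 0.05). Median scaling, under which the median of all probes was -0.61, gave 31 higher and 82 lower, and cyclic loess gave 44 higher and 55 lower.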

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

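Chosen only after the result was seen were the comparison of the mutant effect between ages, the fit of the gut and liver list with the dye term, the random lists, the positions of wild type SLW replicate 8 on single microRNAs, the test of miR-21 across normalizations and the 3 tests of miR-1.

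Gut and liver microRNAs stood 3.05 ± 0.79 higher in the mutants at 30 dpf, on the log2 scale and with the dye term. Unequal dyes are argued against: the list was higher by 3.99 ± 0.69 within Cy3 (4 mutant, 2 wild-type samples) and by 2.31 ± 1.62 within Cy5 (2 mutant, 4 wild-type samples), and 3 of 4 members passed with the dye term, which decides this because the Cy5 value is close to its spread. A different share of gut and liver tissue in the RNA, which may itself be a difference between the fish (growth or feeding), stays open, since the members' deviations from their group means moved together over the 12 samples (median r = 0.938, and 0.808 without wild type SLW replicate 8; 0% of 10000 random lists were higher) and in the 5 samples highest on this list the pancreatic miR-217 was highest too (9.27 to 9.80, others up to 7.63) and the striated muscle list lowest (10.95 to 11.48, others from 11.80). A wrong label on wild type SLW replicate 8 also stays open for that sample: on 15 probes of the sapje cohort it lay at 0.667 of the way from the other SLW samples to the sapje-like samples, at 0.612 on miR-146b, 0.997 on the gut and liver list and 0.0935 on miR-739. A wrong label would lower the difference between the groups, not raise it, and a biological difference between mutants and wild types stays open as untested. The joint movement of the list members does not tell a share of tissue from such a difference. In wild types SW and SLW the list mean was 9.34 and 9.615 at 5 dpf, and 7.26 and 8.76 at 30 dpf. In sapje and sapje-like it was 10.68 and 9.67 at 5 dpf, and 10.21 and 11.87 at 30 dpf. The ages lay on separate arrays, so whether the mutants rose or the wild types fell was not settled. Of the members, miR-194a and miR-194b differ by 2 bases and can share signal.

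miR-21 was 1.61 ± 0.16 higher in the mutants at 5 dpf. Each group at 5 dpf held as many Cy3 as Cy5 samples, so a dye imbalance could not arise by design. The differences were 1.57 ± 0.35 within Cy3 and 1.64 ± 0.37 within Cy5. The choice of normalization or background correction is argued against as the source of the difference, which stayed between 1.21 and 1.61 over 8 alternatives, 6 of them with an adjusted p under 0.05 (highest 0.147). More leukocytes in the mutants stay open as the source. The 2 measured leukocyte probes differed by -0.24 ± 0.25 on average where that explanation needed a rise (13 of 16 values above background). This mean joins miR-150 (-0.50) and miR-223 (0.02), and the miR-142 probes of the list were too dim to be tested. The values argue against a rise of this mean, not against more leukocytes of every kind. A response of the mutant tissue to fibre damage is a possible biological explanation, and it was not tested.

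The mutant effect on miR-1 at 5 dpf was -2.41 in sapje-like minus sapje, a difference between groups by the test of the difference itself. A ceiling of the scanner is argued against, since no miR-1 spot at 5 dpf was brighter than 39081, where other spots reached 62312. An exchange of ranks at the top of the quantile scale is argued against as the whole source: under median scaling, which exchanges no ranks, the difference was -2.42 ± 0.76 against -2.41 ± 0.44, a share of 1.00 ± 0.31, although the call ended there (adjusted p = 0.872) because the standard error grew. A difference between the wild types stays open: sapje-like minus sapje was -0.14 ± 0.31, a share of 0.0567 of the difference between the cohorts. The data are consistent with wild-type groups that differ in miR-1 more than the mutants do, which the groups cannot attribute to background, clutch or handling.

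The mutant effect differed between 30 dpf and 5 dpf for 13 probes. It was more positive at 30 dpf than at 5 dpf for miR-184 (1.59, adjusted p = 0.0131), miR-92a (0.93), miR-739 (4.32), miR-456 (0.91) and miR-430b (0.68). The miR-430b value only restates its fall at 5 dpf, since at 30 dpf it was above background in 0 of 6 mutant and 1 of 6 wild-type samples. The miR-739 value takes in an effect of -0.33 at 5 dpf, where wild type SLW replicate 1 lay far above replicate 2 on this probe. The difference was negative for miR-15b (-1.57), miR-21 (-0.99, adjusted p = 0.0131), miR-27c (-1.43), miR-499 (-2.01), miR-152 (-2.02), miR-26b (-0.91), miR-199* (-1.04) and miR-27a (-0.94). Among probes too dim to be tested, some were above background in mutants and in no wild-type sample: miR-142a-3p, miR-202*, miR-460-3p and miR-461 in 1 mutant sample each and miR-18b* in 2. More went the other way. Above background in 1 wild-type sample each and in no mutant were miR-101b, miR-135a, miR-135b, miR-135c, miR-219, miR-27c*, miR-29b, miR-459, miR-722 and miR-96, and miR-430i in 2. Among control RNAs outside the main comparisons, the 5S-b4 probe was 3.40 higher in sapje-like than in wild type SLW at 5 dpf (adjusted p = 0.0374) and 5S-b5 (-1.10) and 5S-b6 (-1.07) were lower at 30 than at 5 dpf in wild type (each adjusted p = 0.0438).

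Other splits of the samples gave the following. For both mutants at 30 dpf a chance division of the samples is argued against. The real split gave 22 probes and the highest other 12, so that 1 of 100 splits, the real one, gave as many. The splits were a random part of those possible, so chance is not excluded. For age, with the cohorts joined, a chance division is argued against as well (96 probes, highest other 46, 1 of 100 splits), which does not part age from array. The splits are too few to argue against chance for sapje (2 probes, highest other 0, 1 of 10 splits) and sapje-like (15, highest other 4, 1 of 10) at 30 dpf. They are too few as well for the wild types at 30 dpf (1, highest other 1, 2 of 10) and both mutants at 5 dpf (2, highest other 5, 3 of 18). For the wild types at 30 dpf and both mutants at 5 dpf other splits matched or exceeded the real count, so chance stays open there. For the difference between the cohorts' effects at 30 dpf, the real split gave 0, so that all 100 splits gave as many whatever the data, and nothing is decided. The highest of them, 22, exchanges mutant and wild type in 1 cohort and is thereby the joint comparison.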

How the results depend on the processing

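The alternatives chosen only after the data were seen were within-array loess with the array block, the gut and liver list as a covariate, 2 samples left out together, subtraction of the empty-spot median and normexp from the empty spots. Of 91 named results past the threshold, 35 kept their side under all 21 settings other than leaving out a sample, and 0 of their 1827 alternative values changed direction (1558 on the same side, 269 no longer past). Of 7051 alternative values of results not past it, 67 passed and 2 turned. With each of the 20 samples left out in turn, 1625 of 1820 values kept their side and 195 did not. Probes near the level of the empty spots and groups of 2 or 3 samples limit what could be called. Where a value moved, the cause was not tested, except where fewer probes or samples entered the fit.

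Counts of probes past the threshold moved as follows. Cyclic loess gave 0 for sapje and for sapje-like at either age, 0 for both mutants at 5 dpf, 0 for the cohort difference at 5 dpf and 0 for the wild types at 5 dpf. Median scaling gave 0 for sapje, sapje-like, both mutants, the cohort difference and the wild types at 5 dpf, 0 for the wild types at 30 dpf and 13 for both mutants at 30 dpf. It also turned miR-29a (-0.82, adjusted p = 0.0105) and miR-140 (-0.86, adjusted p = 0.00828) in the comparison of ages, where the median of all probes under it was -0.61. Quantile normalization within each age gave 0 for the cohort difference and 5 for the wild types at 5 dpf. Within-array loess gave 1 for sapje at 5 dpf and 0 for sapje-like at 5 dpf, sapje and sapje-like at 30 dpf and the cohort difference at 5 dpf. With the array block added it gave 1 for sapje and 0 for sapje-like at 5 dpf, 5 for sapje at 30 dpf and 0 for the cohort difference at 5 dpf. The authors' value table gave 1 for sapje, 0 for sapje-like, 1 for both mutants, 0 for the cohort difference and 1 for the wild types at 5 dpf, and 0 for sapje and for the wild types at 30 dpf. For the wild types at 5 dpf, no background correction gave 9 and no filter on dim probes 5. Requiring signal above background in all samples kept 81 probes and gave 1 for both mutants and for the wild types at 5 dpf, 1 for sapje and 0 for the wild types at 30 dpf, 44 for age and 3 gene list calls, from fewer probes tested.

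Changes to the fit moved counts too. A dye effect per age gave 14 for both mutants at 30 dpf. Each age fitted alone gave 0 for sapje, sapje-like and the cohort difference and 1 for both mutants and the wild types at 5 dpf, and 1 for sapje, 2 for sapje-like and 8 for both mutants at 30 dpf. Only the groups compared gave 0 for sapje-like, the cohort difference and the wild types and 1 for both mutants at 5 dpf, and 4 for sapje, 0 for sapje-like, 8 for both mutants and 0 for the wild types at 30 dpf. The shared array as a block gave 4 for sapje, 24 for sapje-like and 29 for both mutants at 30 dpf. The median over spots gave 0 for the wild types at 30 dpf. A threshold of 0.1 gave 4, 28 and 38 for sapje, sapje-like and both mutants at 30 dpf and 9 for the wild types at 5 dpf. The gut and liver covariate, which differs between mutants and wild types and so takes out mutant effect, gave 1 for sapje, 0 for sapje-like, 1 for both mutants and 0 for the wild types at 30 dpf. With wild type SLW replicate 1 of 5 dpf and replicate 8 of 30 dpf left out together, counts at 30 dpf were 7 for sapje, 43 for sapje-like, 46 for both mutants and 0 for the wild types, and at 5 dpf 1 for both mutants, 0 for the cohort difference and 1 for the wild types. Camera with an estimated correlation gave 1 gene list call in place of 13. The cohort difference at 30 dpf was 0 in each setting run.

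The replicate block, taking the replicate number as a pairing (consensus correlation 0.319), gave 4 for sapje, 28 for sapje-like and 34 for both mutants at 30 dpf and 2 for the cohort difference at 5 dpf; samples of equal number at 30 dpf did not share an array.

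Leaving out each sample in turn, counts ran from 1 to 7 for sapje, 0 to 10 for sapje-like, 1 to 5 for both mutants, 0 to 3 for the cohort difference and 1 to 28 for the wild types at 5 dpf. At 30 dpf they ran from 0 to 8, 0 to 34, 12 to 42, 0 to 0 and 0 to 1 in the same order, and for age from 83 to 105. The correlation between cohorts ran from 0.0361 to 0.378 at 5 dpf and from 0.685 to 0.838 at 30 dpf, and the gene list calls from 11 to 17.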

Other observations

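No further tests were run for this part. The first 3 principal components of the 167 probes held 54.6%, 20.5% and 8.70% of the variance. The first parted the ages. On the second, where miR-192, miR-122, miR-194a and miR-739 weighed against miR-133c and miR-499, the 6 mutant samples of 30 dpf lay between -8.14 and -0.26. Wild type SLW replicate 8 lay within that range, while replicates 2 and 5 lay at 7.53 and 6.39. On the third, wild type SLW replicate 1 of 5 dpf lay at -9.02 and replicate 2 at 1.44. Its miR-739 level was 13.94, against 8.26 in replicate 2 and 12.67, 11.96 and 13.22 in the sapje-like samples of 30 dpf.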
